A study of Homo sapiens with 4 samples.

How the data were processed

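Polyadenylated RNA was measured by RNA sequencing in 4 libraries labelled as MCF-7, a breast adenocarcinoma line, with 2 control libraries and 2 libraries of cells given macrophage-conditioned medium. Per the labels' protocols, the macrophages were U937 monocytic cells exposed to the phorbol ester PMA at 50 ng/ml for 72 h and washed. Their medium was collected 24 h after fresh medium was added, and the cells labelled MCF-7 received it for 48 h. The U937 cells were grown in RPMI and the MCF-7 cells in DMEM, and the labels do not say which medium the controls received. Libraries were made from 1 µg of RNA with an Illumina TruSeq RNA kit, a kit that does not mark strand.

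The deposited values are raw read counts per gene, 1 file per library, which the authors made before deposit. Per the submitters' processing notes, Trimmomatic 0.38, STAR 2.7.8a, featureCounts and DESeq2 were used with the human builds GRCh38.p13 and hg38, with no role or order given. Per the file headers, the counts came after a STAR mapping step. The column header is the same text in all 4 files, so each file was assigned to its library by the sample it was deposited under. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Each file holds 61541 Ensembl gene IDs in the same order, and 28424 of these have no count in any library. A symbol was found for 61528 IDs. Biotype, position, length and GC content came from GENCODE release 29, which is on GRCh38 and holds 58366 of the IDs. Coordinates below are from that annotation, 1-based.

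Total counts were 17878969 and 15425360 in the control libraries and 18721984 and 14263389 in the macrophage-medium libraries. At these depths 3 counts, the limit that a count of 0 allows, correspond to between 0.16 and 0.21 CPM (counts per 1e6 counts) per library. Limits and ratio intervals made from counts cover counting error only, since reads amplified by PCR are not independent molecules.

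Genes were kept with edgeR's filterByExpr at default settings (a minimum count of 10 and a minimum total of 15), which left 16181 genes. Counts were scaled by TMM, and the groups were compared with edgeR 4.0.16 in R 4.3.3 by a robust quasi-likelihood fit and a two-sided test with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of genes below are from this test unless another tool is named. The model held the group only and left 2 residual degrees of freedom. Fold changes are macrophage medium over control on the log2 scale, with the standard error taken from the fold change and the F statistic. Group values are means of TMM-scaled CPM ± SD over 2 libraries unless the text says CPM of all counts. Where a control group held no counts, the fold was computed against 3 counts over the group and is a lower bound. Where it held 1 to 3 counts, the ratio of summed counts is given with an exact binomial 95% interval. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Where 1 library is left out, p-values rest on the spread between the 2 libraries of the other group alone. The controls differed more from each other than the macrophage-medium libraries did (r = 0.963 and 0.985 across genes). Adjusted p-values without a control library may therefore be too small.

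The rule for named genes and 23 gene lists with 736 genes, all matched to an ID, were fixed before the data were examined. The rule took the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap and whose higher group had a mean of at least 5 CPM. From each list it took up to 3 called members with a mean of at least 1 CPM over the 4 libraries, mixed in direction where the calls were mixed, and filled up to 2 with the most abundant tested members. It also took 10 genes of nanotube formation, PKC, Src, p38 and NF-kB signalling whatever their result. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 23 lists. Members were also counted with p-values "adjusted over the list alone". Alternatives for the lists were an estimated correlation, fry in place of camera, total-count scaling, a replicate block and the loss of each library in turn. Alternatives for genes were DESeq2-type, upper-quartile and total-count scaling, no filter and a stricter filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a fit without robust estimation, a replicate block, and the loss of each library in turn. A fit without mitochondrially encoded genes and a fit with a trend over GC content and exon length removed were added after seeing the data, as were 3 further gene lists.

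The gene test was tested on simulated counts drawn from the means, spread and library sizes of these 4 libraries, for macrophage medium against control over 16181 genes. It called 17 of 100 genes changed 2-fold, 94 of 100 changed 4-fold, and 1 of 15981 left unchanged. A 2-fold change was therefore mostly not detectable with these libraries. The changed genes were drawn only from genes with a mean of at least 5 CPM, so these rates do not cover lower genes. Each simulated gene was given the spread fitted for its abundance, the same in both groups. Spread particular to single genes or to 1 group was not simulated, nor were differences shared by libraries of the same number. The rate of false calls may therefore be higher in the data.

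Reads of near-identical genes can be split or lost in counting, so values of ACTBL2, KRT8, KRT18, HLA-C and the mitochondrial genes, which have close paralogs, pseudogenes or nuclear copies, are uncertain to that extent. Of the 77 named genes, 13 overlap the span of another tested gene (TFPI2, JUNB, KRT18, KRT8, ZYX, PXN, STAT1, RELA, HLA-C, PRDX1, MCM7, TM7SF2 and GPC3). Without strand, reads from such overlaps cannot be assigned to 1 gene.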

Results

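The study was designed to find how macrophages induce tunnelling nanotubes, thin actin-based bridges between cells, in the breast cancer line MCF-7. It compared the transcriptome of 2 control libraries with that of 2 libraries from cells kept for 48 h in medium conditioned by U937-derived macrophages. Total counts ranged from 14263389 to 18721984 per library, and between 25233 and 27188 genes had at least 1 count. Mitochondrially encoded transcripts took 1.81% and 9.48% of the counts in control replicates 1 and 2, and 2.84% and 6.43% in macrophage-medium replicates 1 and 2. Log2 CPM correlated across genes at r = 0.963 between the controls and r = 0.985 between the macrophage-medium libraries, where genes are not independent replicates. Between groups, control replicate 1 correlated with macrophage-medium replicates 1 and 2 at r = 0.963 and 0.958, and control replicate 2 at r = 0.936 and 0.949. Control replicate 1 was thus as close to macrophage-medium replicate 1 as to the other control. A chi-square test against counting noise gave 134 per degree of freedom for the control pair and 39.9 for the macrophage-medium pair, so neither pair was a single library deposited again.

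The levels of lineage genes were read first, as a check of the label. MCF-7 is known as an estrogen-receptor-positive luminal line. ESR1, the estrogen receptor gene, had 0 and 2 counts in the controls and 12 and 3 counts in the macrophage-medium libraries, at most 0.641 CPM of all counts. TFF1, a classical estrogen target, had 0 counts in 3 libraries and 2 counts in macrophage-medium replicate 1. The progesterone receptor gene PGR was at 0.27 ± 0.0144 CPM of all counts in the controls (SD, n = 2) and 1.62 ± 0.205 in macrophage medium. Of 34 epithelial identity genes, 8 were under 1 CPM of all counts in the controls, among them GRHL2 with 0 counts and ST14 at 0.0559, RAB25 at 0.261, CRB3 at 0.27 and OVOL1 at 0.274, and the luminal genes AGR2, AGR3 and TFF3 had 0 counts there. These genes were named after their values were seen. Other luminal and epithelial genes were higher. In the controls GATA3 stood at 28.6 ± 1.54, FOXA1 at 52.5 ± 1.9, EPCAM at 121 ± 54.9, KRT8 at 459 ± 65.9 and CDH1, which encodes E-cadherin, at 9.35 ± 2.55 CPM of all counts. The mesenchymal genes VIM and CDH2, the latter encoding N-cadherin, stood at 285 ± 50.0 and 126 ± 64.3 CPM of all counts. The cells are therefore called "labelled MCF-7" below.

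**Figure D1:**
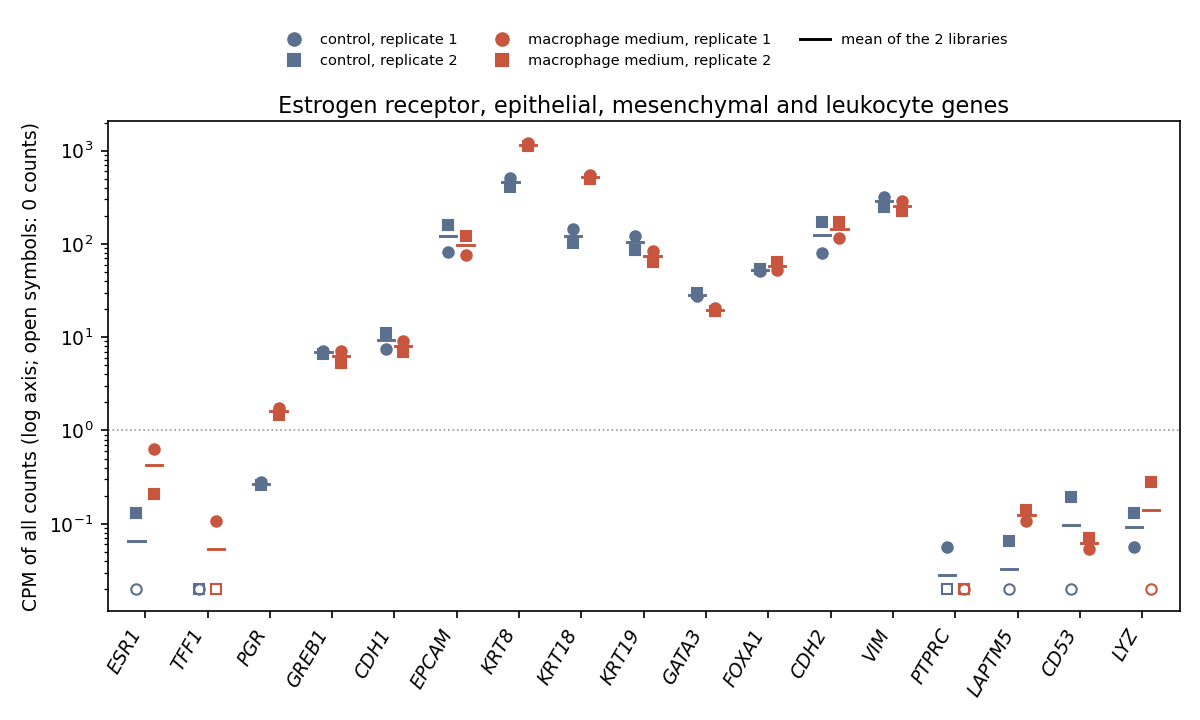
Level of estrogen receptor, epithelial, mesenchymal and leukocyte genes in each library, in CPM of all counts on a log axis, with horizontal bars for the mean of the 2 libraries of a group and open symbols for libraries with 0 counts. ESR1 and TFF1 lie below the dotted line at 1 CPM in all 4 libraries, while no library has less than 80.6 CPM of VIM or CDH2.

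The comparison of macrophage medium with control addressed which transcripts changed in the treated cells. Of 16181 genes tested, 251 were higher and 155 lower in macrophage medium at an adjusted p under 0.05 by edgeR's quasi-likelihood test, and each of these changed at least 2-fold. Among called protein-coding genes that reached 5 CPM in a group, the largest rises by fitted fold change were in KRT79, ARL14, SERPINB2 and TFPI2 and the largest falls in IGFBP5, TXNIP, SSPOP and ITGA8. The order of the rises is uncertain, since KRT79 and ARL14 had 0 control counts and SERPINB2 had 1, and the lower bounds for KRT79 and ARL14 (65.5-fold and 65.2-fold) lie below the fitted 168-fold of TFPI2. The called changes had a median size of 2.11 on the log2 scale. At an unadjusted p under 0.05 there were 2434 genes. The counts depended on single libraries. They were 134 higher and 21 lower without macrophage_medium replicate 1, 141 and 51 without macrophage_medium replicate 2, 967 and 773 without control replicate 2, and 1899 and 1977 without control replicate 1, with 1 residual degree of freedom in each and the lone library assumed to vary like the other group. DESeq2 called 389 higher and 288 lower, limma-voom 208 and 77, and edgeR without a filter on low counts 415 and 342.

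Among the 8 largest rises by fitted fold change, TFPI2, a secreted serine protease inhibitor on chromosome 7 (93885396 to 93890991, GRCh38), rose from 1.97 ± 0.138 to 332 ± 45.2 CPM (log2 fold change 7.39, SE 0.37, adjusted p = 5.05e-06). SERPINB2, which encodes an inhibitor of plasminogen activators (chromosome 18, 63871692 to 63903890), had 1 count in the controls and 490 in macrophage medium, a ratio of 504 with a 95% interval from 90.1 to 20000 (adjusted p = 0.000176). EGR1, an immediate early transcription factor (chromosome 5, 138465490 to 138469315), rose from 6.24 ± 0.224 to 540.0 ± 201 CPM (log2 fold change 6.43, SE 0.40, adjusted p = 2.14e-05). ANKRD1 (chromosome 10, 90912096 to 90921276) rose from 0.59 ± 0.102 to 64.0 ± 60.7 CPM, with 107 CPM in macrophage-medium replicate 1 and 21.1 in replicate 2. Its adjusted p was 0.00116, and 0.326 without control replicate 1. The actin-like gene ACTBL2 (chromosome 5, 57480016 to 57482809) rose from 2.10 and 0.905 CPM in the control libraries to 332 and 143 CPM in macrophage medium (log2 fold change 7.28, SE 0.55, adjusted p = 6.94e-05), with reads that it may share with its near-identical relatives. The keratin gene KRT79 and ARL14, both with 0 counts in the controls, were at least 65.5-fold and at least 65.2-fold higher (adjusted p = 0.000624 and 0.00171). DMRT1 had 2 counts in the controls and 200 in macrophage medium, a ratio of 103 with an interval from 28.1 to 855 (adjusted p = 0.00409).

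Among the 8 largest falls, IGFBP5, which encodes a binding protein of insulin-like growth factors (chromosome 2, 216672105 to 216695525), fell from 444 ± 258 to 6.95 ± 2.30 CPM (log2 fold change -6.00, SE 0.50, adjusted p = 0.000109). TXNIP, a thioredoxin-binding protein gene induced by glucose (chromosome 1, 145992435 to 145996600), fell from 90.1 ± 48.8 to 5.11 ± 1.44 CPM (adjusted p = 0.000349). TSC22D3, a gene known for its induction by glucocorticoids (chromosome X, 107713221 to 107777342), fell from 412 ± 19.1 to 48.8 ± 12.3 CPM (log2 fold change -3.08, SE 0.31, adjusted p = 0.000341). MAP2K6, which encodes a kinase that activates p38 (chromosome 17, 69414698 to 69553861), fell from 22.9 ± 4.12 to 1.76 ± 0.966 CPM (log2 fold change -3.66, SE 0.43, adjusted p = 0.000866). GPC3, which encodes the cell surface proteoglycan glypican-3, fell from 104 ± 52.5 to 12.1 ± 1.84 CPM (adjusted p = 0.00105), and the integrin gene ITGA8 from 9.05 ± 5.40 to 0.661 ± 0.119 CPM (adjusted p = 0.00532). NOXA1 fell from 13.2 ± 12.0 to 1.53 ± 0.324 CPM and SSPOP from 14.5 ± 12.4 to 0.94 ± 0.2 CPM (adjusted p = 0.0295 and 0.00758). These 2 calls were lost with limma-voom (adjusted p = 0.133 and 0.0599), and SSPOP is protein-coding in the annotation used although its symbol marks a pseudogene.

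**Figure D2:**
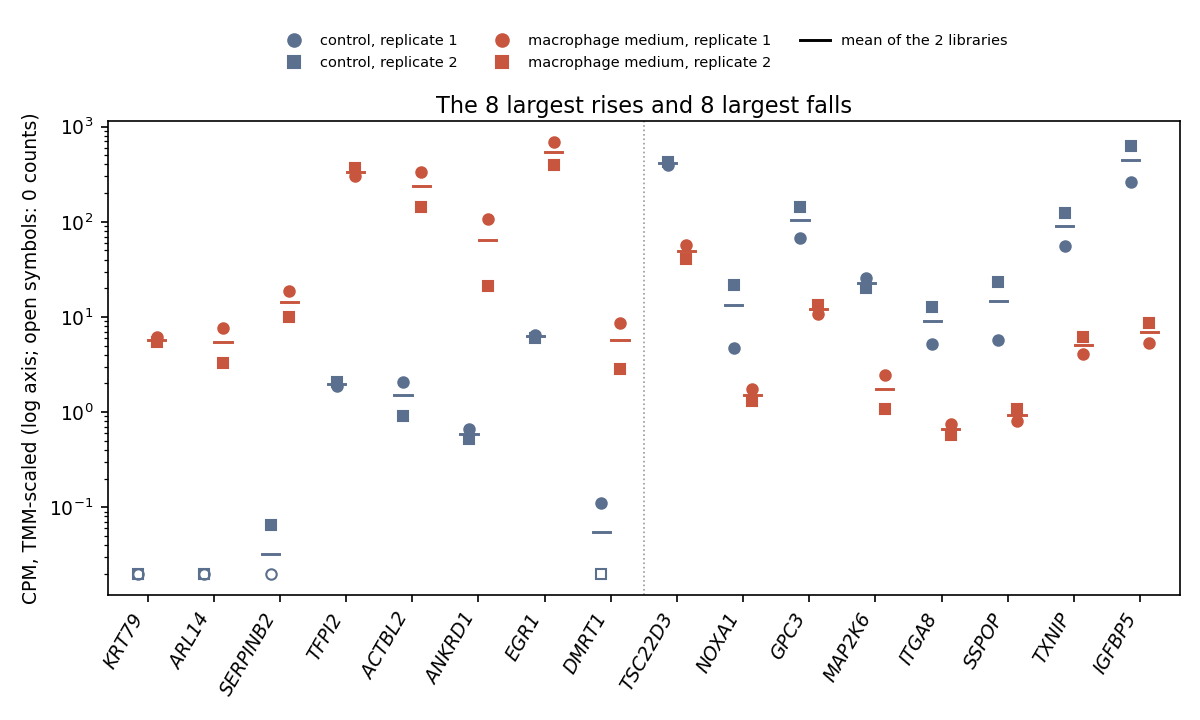
TMM-scaled CPM of the 8 genes with the largest rise (left of the dotted line) and the 8 with the largest fall (right) in each library, on a log axis, with horizontal bars for group means and open symbols for 0 counts. Both macrophage-medium libraries lie above both controls for each rising gene, such as TFPI2 at 300.2 and 364 CPM and KRT79 at 6.17 and 5.41 CPM, and below both controls for each falling gene.

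Gene lists were then compared as groups. Of the 23 lists, 14 passed the threshold by camera at the preset correlation, and all 14 shifted upward relative to the other genes. None of them passed with a correlation estimated from these 4 libraries. That setting leaves each list test with the 2 residual degrees of freedom, so it has little power here. The estimated correlation of the actin list was 0.0108, near the preset 0.01, yet its camera adjusted p went from 2.25e-08 to 0.166. For the actin list, the adjusted p with an estimated correlation therefore does not show that correlation between members undid the shift. Other called lists had higher estimates, such as 0.488 for proteolysis and 0.294 for nanotube genes, or lower ones, such as -0.013 for NF-kB targets. Where the estimate was high, correlation and the few degrees of freedom cannot be told apart as reasons for the loss. By fry, which tests whether a list moves one way on balance, 5 lists passed. They were the immediate early, NF-kB target, and actin lists (adjusted p = 0.0415 each) and the STAT3 and macrophage marker lists (adjusted p = 0.035 each). Members with few control counts, such as TNF, MMP1, AREG and LRG1, passed the filter only through macrophage medium. Such members could only rise, which favours an upward shift of their lists.

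Immediate early and ERK feedback genes, the transcription factors and phosphatases switched on by growth factor signalling, rose in 21 of 35 tested members, with none called lower. With p-values adjusted over the list alone, 26 were higher and 2 lower. Their median log2 fold change was 2.24 (camera adjusted p = 2.12e-58, and adjusted p = 0.162 with an estimated correlation). FOSL1, an AP-1 subunit, rose from 0.824 ± 0.16 to 48.3 ± 2.10 CPM (log2 fold change 5.85, SE 0.35, adjusted p = 1.81e-05), and AREG, which encodes the EGF receptor ligand amphiregulin, from 0.152 ± 0.0592 to 12.2 ± 0.468 CPM (adjusted p = 0.000171).

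NF-kB target genes rose in 8 of 20 tested members and none was called lower. Adjusted over the list alone, 14 were higher and 0 lower. The list has 42 members, and those not tested were too low. The called members CXCL8, CCL2, TNF and IL32 were at 0.19, 0.181, 0.0648 and 0.24 CPM of all counts in the controls. They passed the filter only through macrophage medium and could only rise, which favours an upward shift of the list. The median log2 fold change was 1.53 (camera adjusted p = 3.41e-24, and adjusted p = 0.127 with an estimated correlation). The chemokine gene CXCL8 rose from 0.189 ± 0.19 to 13.8 ± 1.22 CPM (log2 fold change 6.19, SE 0.61, adjusted p = 0.000269) and the cytokine gene IL32 from 0.24 ± 0.027 to 5.97 ± 1.20 CPM (adjusted p = 0.00154). TNF had 2 counts in the controls and 81 in macrophage medium, a ratio of 41.7 with a 95% interval from 11.2 to 350 (adjusted p = 0.0103).

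STAT3 and acute-phase genes rose in 7 of 22 tested members, with none called lower. Adjusted over the list alone, 12 were higher and 0 lower (median log2 fold change 1.00, camera adjusted p = 8.39e-17, and adjusted p = 0.127 with an estimated correlation). JUNB, an AP-1 subunit shared with the immediate early list, rose from 18.1 ± 8.70 to 930.1 ± 363 CPM (log2 fold change 5.68, SE 0.48, adjusted p = 0.000113). TIMP1, which encodes a metalloproteinase inhibitor, rose from 30.1 ± 4.65 to 339 ± 99.5 CPM (adjusted p = 0.000211). LRG1 had 2 counts in the controls and 68 in macrophage medium, a ratio of 35.0 with an interval from 9.32 to 295 (adjusted p = 0.00674, and 0.0525 without macrophage_medium replicate 1).

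The study's question gave the next groups. Of 34 tested genes of tunnelling nanotubes and filopodia, none was called higher and 1, PODXL, was called lower. Adjusted over the list alone, 2 were higher and 1 lower. The 2 higher members, named after their values were seen, were GJA1 and VASP. GJA1 went from 54.8 to 135 CPM of all counts (log2 fold change 1.33, adjusted p over all genes = 0.069). VASP went from 35.5 to 74.9 CPM of all counts (log2 fold change 1.11, adjusted p over all genes = 0.0987). The list's median log2 fold change was 0.22 (camera adjusted p = 0.0332, and adjusted p = 0.643 with an estimated correlation). The shift did not pass without control replicate 2 (median 0.0082, adjusted p = 0.902) or without macrophage_medium replicate 1 (adjusted p = 0.0701), and the median was 0.509 without control replicate 1. PODXL, which encodes the sialomucin podocalyxin, fell from 140.0 ± 50.4 to 50.8 ± 13.3 CPM (log2 fold change -1.46, SE 0.33, adjusted p = 0.0418). Its call was lost with limma-voom, with the GC and length trend removed, and without either macrophage-medium library, where the adjusted p reached 1. The most abundant member, FLNA, which encodes the actin crosslinker filamin A, was at 844 ± 119 and 1387 ± 102 CPM (log2 fold change 0.72, SE 0.32, adjusted p = 0.317). Over the alternatives, the log2 fold change of FLNA lay between 0.571 and 0.941.

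The nanotube genes fixed in advance did not pass the test. TNFAIP2, known as a promoter of nanotube formation, was at 2.53 ± 0.537 CPM in the controls and 2.63 ± 0.864 in macrophage medium, a log2 fold change of 0.05 with a 95% interval from -1.04 to 1.14 (adjusted p = 0.978). Its direction turned without control replicate 1 (-0.0867) and without macrophage_medium replicate 2 (-0.29). MYO10, a filopodial motor gene, was at 128 ± 40.5 and 236 ± 7.09 CPM (log2 fold change 0.89, interval 0.23 to 1.54, adjusted p = 0.174). Its log2 fold change lay between 0.588 and 1.33 over the alternatives. EPS8 was at 27.5 ± 8.69 and 40.8 ± 8.29 CPM (interval -0.09 to 1.22, adjusted p = 0.415), with a log2 fold change between 0.269 and 1.004 over the alternatives. FSCN1, which encodes the actin bundler fascin, was at 203 ± 96.1 and 130.2 ± 36.8 CPM (log2 fold change -0.64, interval -1.42 to 0.14, adjusted p = 0.447). The log2 fold change of FSCN1 was -1.06 without control replicate 2 and 0.0211 without control replicate 1. These intervals are for single genes, without adjustment.

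Actin and focal adhesion genes had positive fold changes in 31 of 39 tested members. 2 were called higher and none lower, and adjusted over the list alone 10 were higher and 1 lower. The median log2 fold change was 0.56 (camera adjusted p = 2.25e-08, and adjusted p = 0.166 with an estimated correlation). ZYX, which encodes the focal adhesion protein zyxin, rose from 73.6 ± 23.1 to 231 ± 12.5 CPM (log2 fold change 1.65, SE 0.30, adjusted p = 0.0153). PXN, the paxillin gene, rose from 30.2 ± 5.27 to 82.8 ± 1.63 CPM (log2 fold change 1.45, SE 0.27, adjusted p = 0.0153). Both calls were lost without either macrophage-medium library (adjusted p up to 0.275 for ZYX and 0.314 for PXN).

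Components of the PKC, Src, p38 and NF-kB pathways were called higher in 3 and lower in 1 of 31 tested members, with the same 3 and 1 adjusted over the list alone (median log2 fold change 0.27, camera adjusted p = 0.00562, and adjusted p = 0.538 with an estimated correlation). The list did not pass without control replicate 2 (median 0.108, adjusted p = 0.197), and its median was 0.448 without control replicate 1. The 3 that rose encode NF-kB subunits. RELB rose from 1.33 ± 0.608 to 26.8 ± 2.46 CPM (log2 fold change 4.31, SE 0.40, adjusted p = 0.00019), NFKB2 from 29.02 ± 0.0245 to 177 ± 19.2 CPM (adjusted p = 0.000511) and NFKB1 from 30.5 ± 1.20 to 96.0 ± 3.40 CPM (adjusted p = 0.00597, lost without either macrophage-medium library at up to 0.0946). The member that fell was MAP2K6, described above. The kinase and NF-kB genes fixed in advance that did not pass were PRKCD (31.7 ± 5.53 and 47.5 ± 3.43 CPM, adjusted p = 0.322), RELA (90.7 ± 16.0 and 124 ± 3.46 CPM, adjusted p = 0.479), SRC (40.7 ± 6.49 and 49.1 ± 3.45 CPM, adjusted p = 0.698), PRKCA (108 ± 16.0 and 102 ± 1.23 CPM, adjusted p = 0.918) and MAPK14, the p38-alpha gene (73.6 ± 6.58 and 63.0 ± 0.916 CPM, adjusted p = 0.755). Over the alternatives, log2 fold changes lay between 0.41 and 0.849 for PRKCD and between 0.278 and 0.72 for RELA.

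**Figure D3:**
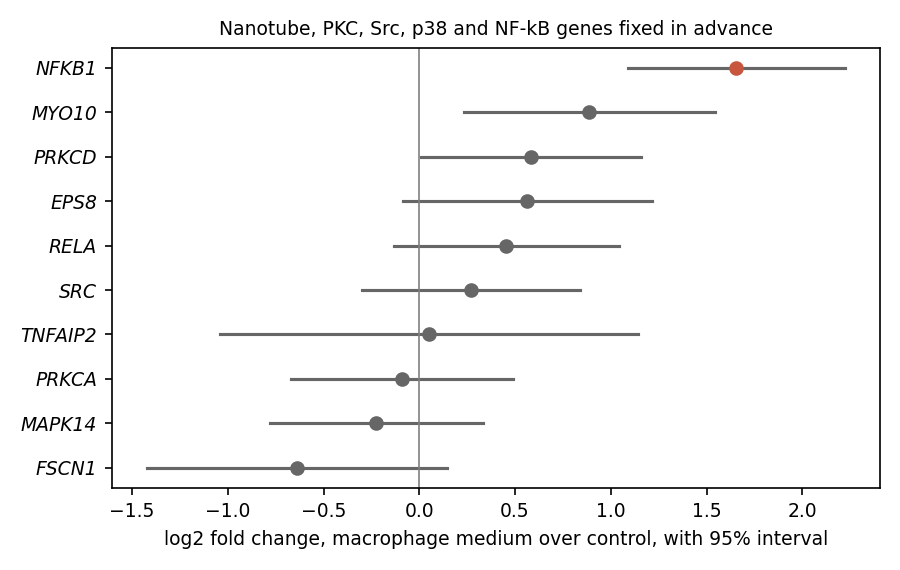
Log2 fold change of the 10 genes fixed in advance, macrophage medium over control, with horizontal lines for 95% intervals of single genes, in red where the adjusted p is under 0.05. NFKB1 at 1.66 is the only gene of the 10 past the threshold, and the intervals of FSCN1, MAPK14, PRKCA, TNFAIP2, SRC, RELA and EPS8 span 0.

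Extracellular proteolysis genes rose in 8 of 24 tested members and none was called lower. Adjusted over the list alone, 11 were higher and 1 lower (median log2 fold change 0.64, camera adjusted p = 1.82e-09, and adjusted p = 0.533 with an estimated correlation). The median depended on single libraries, at 0.0647 without control replicate 1, 0.177 without macrophage_medium replicate 2 and 1.27 without control replicate 2. The collagenase gene MMP1 had 1 count in the controls and 95 in macrophage medium, a ratio of 97.7 with an interval from 17.1 to 3900 (adjusted p = 0.00339). MMP10 had 3 and 125 counts, a ratio of 42.9 with an interval from 14.3 to 211 (adjusted p = 0.00715). Both stayed low, at 2.97 ± 0.59 and 3.78 ± 0.45 CPM in macrophage medium. Like the called members MMP13 and SERPINE1, they passed the filter only through macrophage medium and could only rise, which favours an upward shift of the list. Mesenchymal transition genes rose in 9 of 28 tested members, none was called lower, and adjusted over the list alone 13 were higher and 1 lower (median log2 fold change 0.92, camera adjusted p = 1.63e-15, and adjusted p = 0.21 with an estimated correlation). VIM and CDH2 were not called (log2 fold change -0.12 and 0.21, adjusted p = 0.898 and 0.851). The called members TGFBI, AXL and SERPINE1, at 0.408, 0.464 and 0.158 CPM of all counts in the controls, passed the filter only through macrophage medium. This favours an upward shift of the mesenchymal list. CCN2, a matricellular growth factor gene, rose from 17.5 ± 11.4 to 548 ± 144 CPM (log2 fold change 4.97, SE 0.49, adjusted p = 0.000269), and CD44, the hyaluronan receptor gene, from 4.15 ± 1.81 to 97.3 ± 18.2 CPM (adjusted p = 9.51e-05). SERPINE1, which encodes PAI-1, rose from 0.157 ± 0.144 to 2.12 ± 1.19 CPM (adjusted p = 0.0401). Its call was lost with limma-voom and without macrophage_medium replicate 2, at up to 0.595.

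TGF-beta response genes were called higher in 6 and lower in 1 of 31 tested members, and adjusted over the list alone in 13 and 3 (median log2 fold change 0.61, camera adjusted p = 3.48e-06, and adjusted p = 0.538 with an estimated correlation). CCN2 and SERPINE1 also belong to this list. The inhibitory SMAD gene SMAD6 fell from 63.0 ± 27.8 to 21.4 ± 4.48 CPM (adjusted p = 0.0366), a call lost with limma-voom, with the GC and length trend removed, and without either macrophage-medium library (up to 0.801). Epithelial identity genes were called higher in 2 and lower in 1 of 29 tested members, and adjusted over the list alone in 5 and 1. Their median was -0.09 and their mean 0.20, and the list did not pass by camera, which placed it upward (adjusted p = 0.123). The median turned to 0.152 without control replicate 2 and 0.0853 without macrophage_medium replicate 1. The keratin genes KRT18 and KRT8, which pair in simple epithelia, rose from 121 ± 28.1 to 530 ± 18.8 CPM (adjusted p = 0.00325) and from 455 ± 61.5 to 1173 ± 35.8 CPM (adjusted p = 0.0427). The desmosomal gene PKP3 fell from 55.0 ± 13.8 to 23.4 ± 2.84 CPM (adjusted p = 0.0444). The calls of KRT8 and PKP3 were lost without either macrophage-medium library, at up to 1 and 0.815, that of KRT8 also without robust estimation, and that of PKP3 also with limma-voom and with the GC and length trend removed.

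Estrogen receptor and response genes were called higher in 2 and lower in 1 of 34 tested members, and adjusted over the list alone in 4 and 3 (median log2 fold change 0.17, camera adjusted p = 0.0459, and adjusted p = 0.416 with an estimated correlation). The list did not pass without control replicate 1 (adjusted p = 0.24) or without macrophage_medium replicate 2 (median 0.0029, adjusted p = 0.101), and its median was 0.112 without control replicate 2. The members that rose were AREG, given above, and EGR3, an immediate early factor, from 0.483 ± 0.409 to 12.0 ± 3.99 CPM (adjusted p = 0.00178). Both also belong to the immediate early list, and both passed the filter only through macrophage medium, so they could only rise. RET, a receptor tyrosine kinase gene, fell from 7.37 ± 1.46 to 1.78 ± 0.574 CPM (adjusted p = 0.0415). That call was lost with limma-voom, with the GC and length trend removed, and without either macrophage-medium library (up to 0.632). ESR1 and TFF1 were too low to be tested.

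Stress and metabolic lists changed in few members. Amino acid and unfolded protein response genes were called higher in 1 and lower in 0 of 37 (3 and 1 adjusted over the list alone, camera adjusted p = 0.0317, and adjusted p = 0.643 with an estimated correlation), and the shift did not pass without control replicate 1 (median -0.0325, adjusted p = 0.811) or macrophage_medium replicate 2 (median 0.0029, adjusted p = 0.101). The median was 0.164 with all libraries, 0.66 without control replicate 2 and 0.309 without macrophage_medium replicate 1. The member that rose was ATF3, a stress-induced factor also in the immediate early list, from 31.8 ± 2.19 to 182 ± 36.9 CPM (adjusted p = 0.000821). The chaperone gene HSPA5 was at 481 ± 149 and 1165 ± 403 CPM (adjusted p = 0.105) and passed with DESeq2, without the filter and without either control library. Oxidative stress and metallothionein genes were called higher in 1 and lower in 0 of 24 (3 and 1 adjusted over the list alone, camera adjusted p = 0.00695, and adjusted p = 0.538 with an estimated correlation), with an adjusted p of 0.315 without control replicate 2. Its median of 0.21 became 0.0173 without control replicate 2, 0.703 without control replicate 1 and 0.346 without macrophage_medium replicate 1. HMOX1, the heme oxygenase gene, rose from 18.9 ± 3.18 to 53.4 ± 10.1 CPM (adjusted p = 0.0162, lost without either macrophage-medium library at up to 0.322), while PRDX1 was at 477 ± 195 and 581 ± 73.8 CPM (adjusted p = 0.766, and 0.0136 without control replicate 1).

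Hypoxia and glycolysis genes were called higher in 2 and lower in 1 of 34, the same adjusted over the list alone, and the list did not pass by camera (adjusted p = 0.0642), although it did without control replicate 1 (0.00038) and without macrophage_medium replicate 2 (0.000253). The median turned to -0.0324 without control replicate 2 (0.902, downward) and -0.0169 without macrophage_medium replicate 1 (0.72, upward by camera). The glucose transporter gene SLC2A3 rose from 0.424 ± 0.132 to 7.85 ± 1.01 CPM (adjusted p = 0.00134). NDRG1 rose from 220.0 ± 131 to 848 ± 391 CPM and DDIT4 fell from 329 ± 55.8 to 101 ± 59.95 CPM (adjusted p = 0.0494 and 0.0465). These 2 calls were lost under 4 and 5 of the alternatives, at up to 0.792 and 0.925. They include upper-quartile scaling and the loss of macrophage_medium replicate 1 for both genes. For NDRG1 they also include limma-voom and the fit without robust estimation, and for DDIT4 the removal of the GC and length trend and the loss of control replicate 1 or macrophage_medium replicate 2. p53 target genes were called higher in 3 and lower in 1 of 26, and adjusted over the list alone in 3 and 4 (median log2 fold change -0.24, camera adjusted p = 0.143). The median was -0.433 without macrophage_medium replicate 2 (adjusted p = 0.0394) and -0.0938 without macrophage_medium replicate 1, where camera placed the list upward (0.961). GADD45A rose from 28.7 ± 1.70 to 90.5 ± 8.90 CPM and CDKN1A, the p21 gene, from 45.0 ± 7.10 to 126 ± 14.5 CPM, while DDB2 fell from 138 ± 27.4 to 52.6 ± 8.74 CPM (adjusted p = 0.00648, 0.0155 and 0.0276). These 3 calls were lost without macrophage_medium replicate 1, and those of CDKN1A and DDB2 also without macrophage_medium replicate 2 (up to 0.176, 0.337 and 1).

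Lists of growth and lipid synthesis did not pass. None of 43 proliferation and cell cycle genes was called, also adjusted over the list alone (median log2 fold change -0.11, camera adjusted p = 0.453). The direction turned with the library left out, with a median of -0.206 without control replicate 2 (adjusted p = 0.0022, downward) and 0.192 without control replicate 1 (0.13, upward). MKI67 was at 619 ± 73.6 and 505 ± 65.1 CPM (adjusted p = 0.716), and MCM7 at 784 ± 74.5 and 771 ± 2.37 CPM (adjusted p = 0.982). Of 24 cholesterol biosynthesis genes, 1 was called lower and 0 higher, the same adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 0.386, downward). The median turned to 0.0058 without control replicate 2 (0.315, downward by camera) and 0.0396 without macrophage_medium replicate 1 (0.731, upward). TM7SF2, a sterol reductase gene, fell from 54.7 ± 20.2 to 18.0 ± 3.96 CPM (adjusted p = 0.0242, lost without either macrophage-medium library at up to 0.714), and DHCR24 was at 297 ± 83.0 and 469 ± 226 CPM (adjusted p = 0.448, and 0.00444 without control replicate 2). None of 22 fatty acid and SREBP1 genes was called, also adjusted over the list alone (camera adjusted p = 0.33). FASN was at 1257 ± 506 and 1063 ± 120.1 CPM and SCD at 1112 ± 304 and 657 ± 195 CPM (adjusted p = 0.824 and 0.338, the latter 0.00675 without control replicate 1).

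Interferon-related lists held no called gene. None of 25 type I interferon-stimulated genes was called, also adjusted over the list alone (camera adjusted p = 0.143). STAT1 was at 63.0 ± 10.0 and 92.2 ± 11.3 CPM (adjusted p = 0.373, and 0.0122 without control replicate 1) and LY6E at 90.7 ± 9.33 and 99.0 ± 13.9 CPM (adjusted p = 0.882). None of 22 antigen presentation and interferon-gamma genes was called, also adjusted over the list alone, although the list shifted upward by camera (median log2 fold change 0.37, adjusted p = 0.00239, and adjusted p = 0.538 with an estimated correlation), with an adjusted p of 0.208 without control replicate 1. The median was 0.83 without control replicate 2 and 0.633 without macrophage_medium replicate 1. B2M was at 119 ± 59.5 and 218 ± 39.7 CPM (adjusted p = 0.269) and HLA-C at 202 ± 70.6 and 268 ± 47.4 CPM (adjusted p = 0.615). Over the alternatives, log2 fold changes lay between 0.508 and 1.49 for B2M and between 0.16 and 0.804 for HLA-C.

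Markers of other cells were low. Of 33 macrophage and monocyte markers, 31 were under 1 CPM of all counts in the controls and 5 could be tested, 3 of them (ITGAX, NCF2 and ITGAM) only because their counts in macrophage medium passed the filter, which favours an upward shift of the list. Of these 5, 2 were called higher and 0 lower, and adjusted over the list alone 4 and 0 (median log2 fold change 3.54, camera adjusted p = 0.000169, and adjusted p = 0.21 with an estimated correlation or 0.0547 without control replicate 1). The median was 2.32 without control replicate 1, 1.92 without control replicate 2, 2.24 without macrophage_medium replicate 1 and 2.02 without macrophage_medium replicate 2. The called members, named after their values were seen, were the integrin gene ITGAX, with 2 and 44 counts (ratio 22.6, interval 5.90 to 193), and the NADPH oxidase gene NCF2, with 3 and 51 counts (ratio 17.5, interval 5.66 to 87.6). CORO1A was at 8.47 ± 2.37 and 15.5 ± 2.50 CPM (adjusted p = 0.249, and 0.00355 without control replicate 1) and CD4 at 1.12 ± 0.336 and 0.634 ± 0.0813 CPM (adjusted p = 0.609). Of 17 fibroblast and endothelial markers 3 could be tested and none was called, also adjusted over the list alone (camera adjusted p = 0.384). COL1A1 was at 27.6 ± 0.58 and 36.8 ± 2.90 CPM and EMCN at 2.75 ± 0.688 and 3.18 ± 0.289 CPM (adjusted p = 0.493 and 0.886).

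None of the 13 mitochondrially encoded transcripts was called, also adjusted over the list alone. Their median and mean log2 fold changes were both -0.18, while camera placed the list upward (adjusted p = 0.805). MT-CO1 was at 12844 ± 12740 CPM in the controls and 9358 ± 6463 in macrophage medium, and MT-CO2 at 6302 ± 5506 and 6505 ± 3537 (adjusted p = 0.835 and 0.983). Without control replicate 2 both were higher in macrophage medium, with log2 fold changes of 1.28 and 1.42 (adjusted p = 0.00224 and 0.000344). The spread within each group exceeded the difference between groups, and the direction turned with the libraries used. The median was 1.46 without control replicate 2 (adjusted p = 5.5e-17), 0.263 without macrophage_medium replicate 1 (0.00109), -0.849 without control replicate 1 (0.00016) and -0.782 without macrophage_medium replicate 2 (0.0101).

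**Figure D4:**
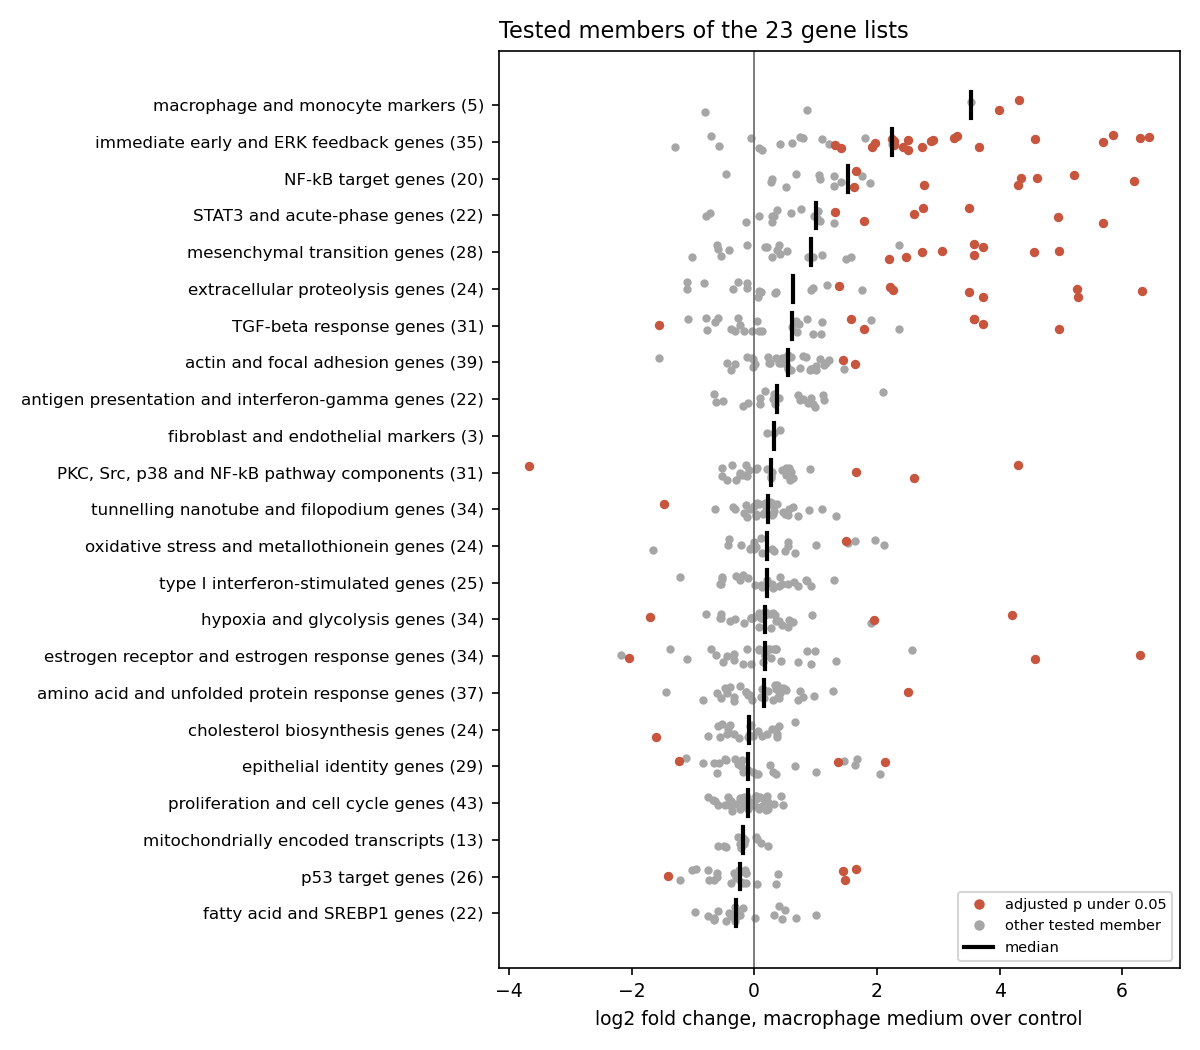
Log2 fold change, macrophage medium over control, of each tested member of the 23 gene lists, with the number tested in brackets, red points for an adjusted p under 0.05 and black bars for list medians. The immediate early list holds 21 red points and a median of 2.24, while the proliferation list holds none among 43.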

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

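The fits without mitochondrially encoded genes and with the GC and length trend removed were chosen after seeing the data, and the other alternatives were planned. Leaving aside the losses of 1 library and the replicate block, 3 alternatives moved a count of called genes by over 1.5 times from 251 higher and 155 lower. Without a filter on low counts, 33117 genes were tested, 415 were higher and 342 lower, all at least 2-fold. DESeq2 called 389 higher and 288 lower, with 276 of the lower genes at least 2-fold, and shared 246 and 154 genes with the counts reported. Limma-voom called 77 lower, all at least 2-fold and all shared. The cause of the last 2 was not tested. Losing 1 library gave 134 to 1899 higher and 21 to 1977 lower genes, and 134 to 887 and 21 to 1361 at least 2-fold, from fits with fewer samples. In each alternative, those of the 406 called genes that were tested kept their direction. This was largely fixed beforehand, since the groups of all 406 did not overlap, and it is no measure of robustness.

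The replicate numbers are shared by both groups, but the labels tie them to no day or batch and there are only 2 pairs. The difference between libraries 1 and 2 correlated across genes between the groups at r = 0.366. With a replicate block, 892 genes were higher and 1044 lower, 507 and 605 of them at least 2-fold, with 1 residual degree of freedom. The block called 13 lists, lost the estrogen list (adjusted p = 0.0502) and turned the median of the mitochondrial list to 0.184. It added calls of HSPA5 (adjusted p = 5.95e-05), MYO10 (0.00285), B2M (0.0018), CORO1A (0.0296) and SCD (0.0357) among the named genes.

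Of 14 lists past the threshold, 0 passed with an estimated correlation, a test with 2 residual degrees of freedom, and 5 with fry. Losing 1 library kept 10 of the 14 without control replicate 1, 11 without control replicate 2, 13 without macrophage_medium replicate 1 and 12 without macrophage_medium replicate 2, and added 1 to 3 others. Of the 50 called named genes, 30 passed under each alternative, 20 were lost under at least 1 and 0 reversed. The lack of reversals was largely fixed beforehand, since the groups of each called gene did not overlap. Of the 27 others, 15 passed in the same direction under at least 1, and MT-CO1 passed in the opposite direction without control replicate 2. The reversals were in genes and lists that were not called, except the amino acid and unfolded protein response list. The log2 fold change of MCM7 was 0.0116 with DESeq2-type scaling and 0.0116 with DESeq2, that of MT-CO2 was -0.0043 with upper-quartile scaling, and with the GC and length trend removed MCM7 was at 0.0714 and PRKCA at 0.0214. Losing 1 library moved log2 fold changes between -0.0885 and 0.853 for PRDX1, -0.0027 and 0.308 for LY6E, -0.294 and 0.399 for TNFAIP2, -0.616 and 1.42 for MT-CO2, -0.127 and 0.149 for MCM7, -0.243 and 0.1397 for PRKCA, -0.612 and 0.313 for FASN, -1.38 and 1.28 for MT-CO1, and -1.06 and 0.0211 for FSCN1. It moved list medians between -0.206 and 0.192 for proliferation, -0.129 and 0.152 for epithelial identity, -0.0324 and 0.588 for hypoxia, -0.0325 and 0.660 for the amino acid and unfolded protein response, -0.348 and 0.0396 for cholesterol, and -0.849 and 1.46 for mitochondrial transcripts. Medians of called lists that kept their sign but moved by over 1.5 times lay between 0.0647 and 1.27 for proteolysis, 0.0173 and 0.703 for oxidative stress, 0.0029 and 0.237 for estrogen response, 0.257 and 0.83 for antigen presentation, 0.108 and 0.448 for PKC to NF-kB components, 0.0082 and 0.509 for nanotubes, and 1.92 and 2.32 for macrophage markers. The cause was not tested. At this depth and with 2 libraries per group, the test called 17 of 100 simulated 2-fold changes. Whether depth or the number of libraries sets this limit was not tested.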

Other observations

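The tests of another cell line, of embryonic kidney cells, of a shared day or batch, of carried-over macrophage RNA and of the control medium were chosen only after the result was seen, as were the count of calls kept without mitochondrial genes, the intervals of list medians, the test of a fall as large as that of TSC22D3 and the tests without members of the fixed lists.

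Several further genes, named after their values were seen, changed. The cytokine gene IL11 rose from 0.927 ± 0.609 to 71.8 ± 33.9 CPM (SD, n = 2) and LIF from 4.54 ± 1.90 to 30.8 ± 17.0 CPM. The receptor gene IL6R rose from 6.40 ± 1.64 to 43.2 ± 5.66 CPM, and the chemokine gene CCL7 and the receptor gene IL7R, with 0 counts in the controls, were at least 21.3-fold and at least 37.0-fold higher. The laminin gene LAMB3 rose from 0.612 ± 0.226 to 19.6 ± 4.43 CPM, the annexin genes ANXA1 and ANXA2 from 1.69 ± 0.567 to 33.0 ± 11.6 and from 67.1 ± 24.5 to 276 ± 16.9 CPM. Among falling genes were HES5, from 3.88 ± 0.647 to 0.241 ± 0.0352 CPM, and HEY1, from 46.2 ± 11.01 to 19.9 ± 0.445 CPM, and LGR5, from 63.7 ± 34.0 to 16.8 ± 4.53, SFRP2, from 19.9 ± 10.1 to 4.61 ± 0.115, and WNT5A, from 38.3 ± 22.8 to 10.2 ± 1.91 CPM. Each had an adjusted p under 0.05 by edgeR.

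CCN1, CCN2, ANKRD1 and MYOF, known targets of the coactivator YAP, rose together, which led to the hypothesis that YAP targets may rise as a group. The 18 other members of a YAP target list had a median log2 fold change of 0.98, with 5 called higher and 0 lower (camera adjusted p over 3 added lists = 1.75e-08). With an estimated correlation the adjusted p was 0.0728. Of these, 3 (GADD45A, AXL and TGFB2) are also in the fixed lists, so their values had been computed earlier, and without them the adjusted p was 2.55e-06. Many such genes also respond to AP-1, so the list does not single out YAP. The fall of TSC22D3 led to the hypothesis of a fall in glucocorticoid-responsive genes. The 11 other members went both ways, 7 with a positive and 4 with a negative fold change, with a median of 0.24, 3 called higher (SGK1, DUSP1 and ERRFI1) and 0 lower (adjusted p = 0.000531 upward, 0.136 with an estimated correlation). The interval of the median (98.8%, order statistics) ran from -0.634 to 2.45, which argues against a fall of about the size of that of TSC22D3 (-3.08). The median met the bound set beforehand against any group fall, a median at or above 0, by less than this spread, which leaves a smaller fall open. Without the 4 members that are also in the fixed lists (DUSP1, MT2A, MT1X and ANGPTL4) the adjusted p was 0.000851, upward. The fall of DBP, a clock output gene, from 13.9 ± 2.14 to 2.88 ± 0.6 CPM led to the same question for clock genes. None of the 11 other members was called (median -0.21, adjusted p = 0.446), which leaves it open.

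ESR1 and TFF1 were nearly without counts in all 4 libraries labelled MCF-7. MTAP lies in a chromosome 9 segment known to be deleted in MCF-7 together with CDKN2A. MTAP had at least 7.78 CPM of all counts in each library. CDKN2A had a mean of 7.31 in the controls and at least 5.9 in each library. These values argue against MCF-7 cells that merely lost the receptor, and against libraries of MCF-7 cells alone. The test of another line under the MCF-7 label did not decide, since 23.5% of the epithelial list was under 1 CPM in the controls, between the bounds set for it. No reference profile of MCF-7 was used here, so which cells these were stays open. IRS4, an insulin receptor substrate gene first found in the embryonic kidney line HEK293, had a mean of 1700.0 CPM of all counts in the controls. In macrophage medium the IRS4 mean was 642.5, with 488.4 and 796.5 in replicates 1 and 2. The cause of this difference was not tested. Kidney origin may explain the high IRS4 but cannot be told apart from another IRS4-expressing line, since the deciding adenoviral genes were not counted. No biological explanation other than loss of the receptor was tested.

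Immediate early, AP-1 and NF-kB genes were high after 48 h, a time at which such genes have often returned to baseline. A bias with GC content or length is argued against for the rises, since the called higher genes had 101% of their median log2 fold change after that trend was removed. Of the 155 lower calls, 115 stayed called in that fit, so the same is not shown for the falls. RNA carried over from macrophages is argued against as the source of these genes, since none of PTPRC, LAPTM5, CD53, TYROBP, LYZ, SRGN and CD68, known as abundant in macrophages, exceeded 0.28 CPM of all counts in a treated library. Other macrophage markers went the other way, with ITGAX and NCF2 called higher at 1.33 and 1.51 CPM of all counts, and ITGAM at a log2 fold change of 3.54 (adjusted p = 0.0573), but these 3 passed the filter only through their counts in the treated libraries, so the upward shift of the marker list (camera adjusted p = 0.000169, 0.21 with an estimated correlation and 0.0547 without control replicate 1) weighs little, and the source of these low counts was not tested. A component of the medium other than macrophage products, such as remaining PMA or a difference of base medium, stays open, because the labels describe the medium of 0 of the 2 control libraries, and cannot be told apart from secreted macrophage factors, the biological explanation that the design names.

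Libraries numbered 2 held a larger mitochondrial share than libraries numbered 1 in both groups. GC bias between the numbers is argued against by a Spearman rho across genes of 0.0475 in the controls, with 0.102 in macrophage medium. Mitochondrial counts as a cause of the treatment calls are argued against, since 405 of the 406 called genes stayed called without those genes, although the total of 550 calls lay between the bounds set beforehand. A shared day or batch behind each number also stays open, because the differences correlated between groups at r = 0.366 but the labels name no batch. No biological explanation was tested.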
